A study of Caenorhabditis elegans with 6 samples.

How the data were processed

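Gene expression was measured in whole wild-type N2 Caenorhabditis elegans on Affymetrix arrays of biotin-labelled single-stranded cDNA made from 3.5 ng of total RNA. There were 6 arrays in 3 groups of 2, from animals kept in water, in 100 µM Ponceau Red or in 100 µM tartrazine. The exposure lasted 48 h at 20 °C in S medium and began 16 to 18 h after hatching. Each sample was assigned to its group from its title.

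The values analysed were log2 signals per transcript cluster that the authors computed with RMA over the 6 arrays, RMA being named in the submitters' processing notes and in the column names. The RMA version, its background options and the annotation release were not given in the sources used here. A second deposited table of log2 RMA signals, 1 column per labelled sample, was compared with the first. It differed from it by a median of 0.21 log2 in the water arrays and 0.21 in the Ponceau Red arrays but by -0.06 in the tartrazine arrays. The offsets per probe set correlated at 0.82 between water and Ponceau Red and at 0.23 between water and tartrazine, a pattern that separate RMA runs would give, although the sources used here do not say so. The table was used only as an alternative.

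The column names of the table over 6 arrays number the arrays 1 and 2 for water, 2 and 3 for Ponceau Red and 1 and 2 for tartrazine, and arrays are named by these numbers here. The names of water array 1 and tartrazine array 2 carry a second number, 3 and 1, whose meaning was not given in the sources used here and which was not read. The labels number the trials 1 and 2 in every group. Within each group the values of the 2 tables were matched column by column, with correlations of at least 0.92 for signals less the group mean, which put Ponceau Red array 2 in labelled trial 1 and array 3 in trial 2 and left the other numbers as they are. With labelled trials matched, the difference between the arrays of a group correlated across probe sets at 0.04 between water and Ponceau Red. It did so at 0.16 between water and tartrazine and -0.04 between Ponceau Red and tartrazine. The fit reported therefore used no block, and the labelled trial was entered as a block in an alternative planned from the start. This reason comes from the data, so the use of no block is not counted among the choices fixed beforehand. It matters: 796 probe sets passed for Ponceau Red and 1208 for tartrazine without the block, and 312 and 423 with it.

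The authors also deposited 1 analysis of variance table per colorant. Each holds a linear ratio of treated over control (a fold change), an F score with its sums of squares as scores, and an unadjusted p-value, by the authors. The p-value column of the deposited Ponceau Red table holds a question mark in place of a number for 485 other probe sets. The Ponceau Red table lists 29317 probe sets. That for tartrazine lists 1746, all with an unadjusted p under 0.05. In both tables the sums of squares, ratios and F scores fit 3 error degrees of freedom and groups of 3 and 2 arrays, so 5 arrays. The authors' tool and the identity of the array beyond the 4 analysed here were not given in the sources used here.

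Of 29317 probe sets, 27568 had a gene name and were tested, and 1749 unnamed ones were left out. Names came from a RefSeq table of assembly WBcel235, matched by accession for 24021 probe sets and by symbol for 3063. For 484 probe sets the name was taken from the deposited table alone. The tested probe sets carry 26975 distinct names, 19761 of them are coding, 197 were assigned to more than 1 gene and 513 were marked for cross-hybridisation. The symbol differed from that in the deposited table for 2107. Vitellogenin, major sperm protein, histone and collagen genes share sequence, so that the signal of 1 member can include others.

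Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with 3 residual and 1.79 prior degrees of freedom) on all 6 arrays, with 3 contrasts and a moderated F test, all two-sided. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05. No filter on low signal was used. Errors are the standard errors of the fit, and intervals are at 95%.

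Before the data were examined, the tests (apart from the use of no block), the processing alternatives, 40 gene lists written from textbook knowledge and the rule for named genes were fixed. The lists cover xenobiotic metabolism, stress and immune responses, cuticle and moulting, reproduction, tissues, energy and protein metabolism, and large gene families. All 40 had at least 3 measured genes and were tested with camera, with a preset correlation of 0.01, on 1 probe set per gene, Benjamini-Hochberg adjusted over the lists. Camera with an estimated correlation and fry were run beside it. By the rule, the text names coding probe sets with 1 gene name: up to 10 per direction with the largest change among those that passed and whose arrays did not overlap between groups, up to 4 members of each list that passed, up to 2 of each other list described, and 10 common reporter genes. Genes named outside the rule are said to be so.

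The correlation of the responses to the colorants was set beside 100 simulations of unchanged groups that share the same controls, since both responses use the same water arrays. For the overlap of calls, 20 simulated sets were ranked by p, and as many probe sets as were called were taken from each, a test added after seeing the data. The fit was tested on 1 simulated set in which, among 27568 probe sets, 100 changed by 1 log2 and another 100 by 3 log2. For tartrazine against water over 6 arrays it recovered 0% of changes of 1 log2 and 51% of changes of 3 log2, with 1 false call in the set. Each simulated probe set took its estimated spread as the true one, and fewer changed than the 1208 called in the data. The shares recovered therefore need not hold for the data. For a simulated shift of 1 log2 in a list of 98 genes, camera gave an adjusted p of 7.81e-54 and called 0 of the other lists that shared no gene with it. The simulated genes varied independently. In the data the estimated correlation was 0.31 for that list, the moulting genes, 0.91 for the germ line and 1.00 for the vitellogenins. The simulation therefore cannot show how often camera calls lists falsely in these data.

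Alternatives were centring each array on its median, a further quantile normalization, filters on low signal, a trended and a robust prior, 1 probe set per gene, other thresholds, only the 4 arrays of a comparison, the second deposited table, the labelled trial as a block, and leaving out each array in turn. A replicate block by the number in the column names, the series of list tests over 4 arrays and the further quantile normalization of the list tests were added after seeing the data. Leaving out an array leaves 1 group with a single array, which is then assumed to vary like the other groups. Tests of outlying samples and of other splits of the samples were not applicable to groups of 2.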

Results

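Transcript levels were measured in whole C. elegans of the wild-type strain N2 that had been kept from the first larval stage in water or in 1 of 2 food colorants. The labels give their age as 3 days and their stage as young adult for every group. Only the labels give this stage. The yolk gene vit-2, a gene of adults, read 1.75 and 2.22 in water and 9.64 and 9.99 in tartrazine. The readings that are low for the labelled young adult stage are those of both water arrays, and that of Ponceau Red array 3, at 1.83. A difference in stage between the groups is therefore not excluded, whatever the labels say, and its cause was not tested. Ponceau Red and tartrazine are both synthetic azo dyes, here given at 100 µM for 48 h. Each of the 3 groups had 2 arrays. Signals ran from 0.44 to 11.65 log2. The median signal was 2.40 and 2.35 in the water arrays, 2.13 and 2.17 in the Ponceau Red arrays and 2.22 and 2.13 in the tartrazine arrays. Log2 changes are given on the deposited scale. The array medians differed by -0.22 log2 between Ponceau Red and water and by -0.20 between tartrazine and water, so a change relative to the array medians is higher than the printed one by these amounts. The median change over all tested probe sets was 0.06 log2 in Ponceau Red and 0.02 in tartrazine, so the typical probe set did not show this shift. Where a group reads near or below the array medians, the printed change is a lower bound. The number of arrays limits the precision: the median 95% interval of a log2 change reached 0.65 to either side. The p-values measure only the spread between these 6 arrays.

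Across probe sets, which are not independent replicates, the water arrays correlated at 0.987 and 451 probe sets differed by more than 2-fold between them. The tartrazine arrays correlated at 0.982, with 800 such probe sets. The Ponceau Red arrays correlated at 0.844, and 6605 probe sets differed by more than 2-fold between them. Ponceau Red array 2 correlated at 0.991 with tartrazine array 2, with 192 probe sets over 2-fold apart. Ponceau Red array 3 correlated at 0.915 and 0.931 with the water arrays and at 0.811 and 0.828 with the tartrazine arrays.

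**Figure D1:**
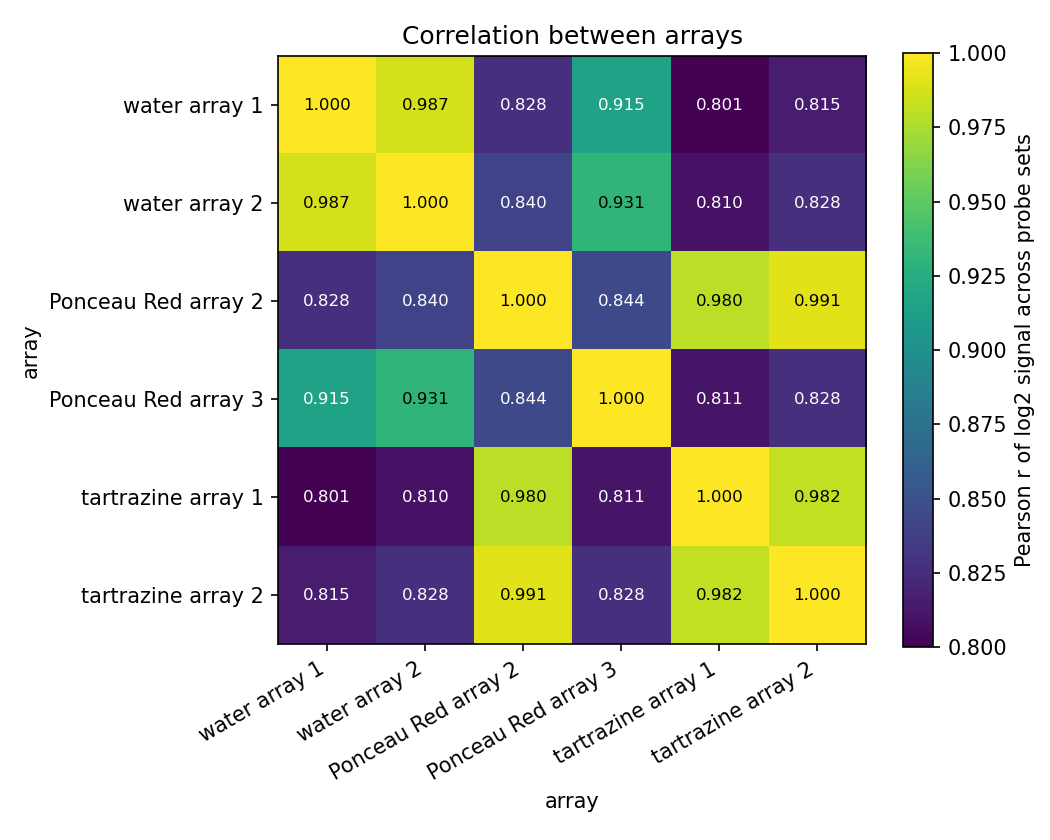
Pearson correlation of RMA signals (log2) across the tested probe sets for each pair of the 6 arrays. The value within a group was 0.987 for water, 0.982 for tartrazine and 0.844 for Ponceau Red.

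The comparison of Ponceau Red with water asks which transcripts differ after exposure to this colorant. Genes of the cuticle, the collagen-rich outer coat that worms replace at each moult, were among those that fell. The cuticle collagen gene sqt-2 (chromosome II, 23325 to 24458, assembly WBcel235), which affects body shape, fell by 4.67 ± 0.25 log2 (SE, n = 2 arrays per group; 25.4-fold; limma adjusted p = 0.00515). The collagen genes col-41 and col-65 fell by 4.52 ± 0.23 and 4.45 ± 0.31 log2. The hedgehog-related gene wrt-4 (chromosome X, 15752257 to 15757269) fell by 4.33 ± 0.21 log2 (limma adjusted p = 0.00515). For 773 of the probe sets that passed, a further control implied by the authors' tables, described below, lay nearer to Ponceau Red. It lay nearer to water for 23. In all, 796 probe sets passed in limma, of which 38 rose and 758 fell. This count moved with every array left out. It was 0 without water array 1 and 0 without water array 2, with 2248 and 2812 probe sets at an unadjusted p under 0.05. It was 3134 without Ponceau Red array 2 (1376 up, 1758 down), 7205 without Ponceau Red array 3 (3607 up, 3598 down) and 127 without either tartrazine array (2 up, 125 down), so the excess of falls depended on the arrays used. With the labelled trial as a block it was 312 (8 up, 304 down). With the second deposited table it was 684 over 6 arrays, and 0 over the 4 water and Ponceau Red arrays, with 3472 at an unadjusted p under 0.05 in limma.

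Among 173 measured cuticle collagens, 33 fell, 0 rose and 140 did not pass in Ponceau Red, 40 had a positive difference, and 59 fell and 3 rose when adjusted over the list alone. Their median was -1.33 log2 (camera adjusted p = 7.49e-17, adjusted p = 0.752 with an estimated correlation, fry adjusted p = 0.0126). Of 98 moulting and hedgehog-related genes, 12 fell and 0 rose, or 23 and 0 adjusted over the list alone. Their median was -0.77 log2 (camera adjusted p = 1.57e-12, adjusted p = 0.994 with an estimated correlation). The hedgehog-related gene grl-21 fell by 4.13 ± 0.44 log2, a call that ended without either tartrazine array (limma adjusted p = 0.0608) and with the labelled trial as a block. The medians of these lists were -0.75 and -0.35 log2 without Ponceau Red array 2, and -1.34 and -1.47 without array 3. The count of collagens that fell was 10 without either tartrazine array, 64 without Ponceau Red array 2 and 97 without array 3, and that of moulting genes 4, 30 and 59. With array 3 left out 22 collagens and 2 moulting genes also rose, and with array 2 left out 2 and 3. Of 244 C-type lectins, carbohydrate-binding proteins that include immune effectors, 11 fell and 0 rose, or 11 and 1 adjusted over the list alone. The count of lectins that fell was 1 without either tartrazine array, 26 without Ponceau Red array 2 (12 rose) and 42 without array 3 (23 rose). The lectin gene clec-125 fell by 3.88 ± 0.24 log2 (limma adjusted p = 0.00606, or 0.0525 without either tartrazine array). The lectin list had a median of -0.11 log2, which turned to 0.11 with each array centred on its median (camera adjusted p = 0.00306, adjusted p = 0.994 with an estimated correlation, and camera adjusted p = 0.0681 without Ponceau Red array 3). Without either water array 0 probe sets passed in limma.

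Genes of reproduction differed between the Ponceau Red arrays. The vitellogenins, yolk proteins made in the intestine of adult hermaphrodites, had a median 8.71 log2 above the water mean in Ponceau Red array 2 and 0.03 in array 3. The signal of vit-2 (chromosome X, 5101032 to 5106169) was 10.76 and 1.83 in these arrays and 1.75 and 2.22 in water. Its difference of 4.31 ± 2.89 log2 did not pass (limma adjusted p = 0.563), nor did the list of 6 vitellogenins (median 4.31 log2, camera adjusted p = 0.0832). Without array 3 this list passed, with 6 rising (median 8.71 log2, camera adjusted p = 5.53e-09), and without array 2 it lay at 0.03 (camera adjusted p = 0.831). Oocyte and eggshell genes lay 5.08 log2 above water in array 2 and -0.34 in array 3, and germ line genes 3.31 and -0.36. DNA damage response genes lay at 1.91 and -0.02, high and low in the same arrays as the germ line genes. Of 24 oocyte and eggshell, 24 germ line and 22 DNA damage genes, 0 passed in limma, over all genes or adjusted over the list alone, and of all probe sets 4096 had an unadjusted p under 0.05. The counts rising without Ponceau Red array 3 were 23, 22 and 18, with 0, 1 and 0 falling, and without array 2, 0, 0 and 1 rose and 3, 2 and 0 fell. The median of the oocyte list was 2.38 log2 (camera adjusted p = 0.00306), that of the germ line 1.57 (camera adjusted p = 0.0162) and that of DNA damage 1.01 (camera adjusted p = 0.00306), each with adjusted p = 0.994 with an estimated correlation. Without Ponceau Red array 2 these medians were -0.34, -0.36 and -0.02 (camera adjusted p = 0.0525, 0.0419 and 0.885), so the germ line list passed in the other direction. Without array 3 they were 5.08, 3.31 and 1.91. The germ line call also ended without water array 2 (camera adjusted p = 0.0604), and all 3 calls ended with each array centred on its median (camera adjusted p = 0.201, 0.374 and 0.116).

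**Figure D2:**
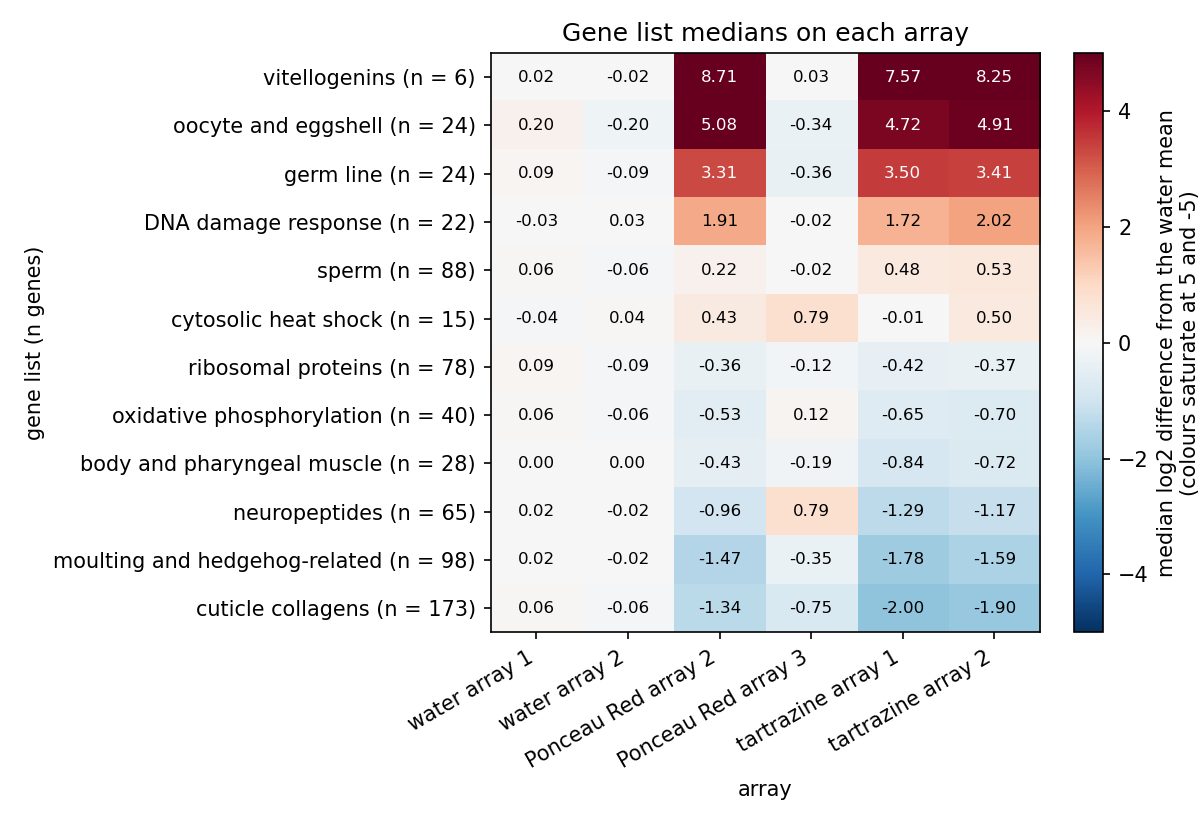
Median log2 difference from the water mean over the genes of each list, for each of the 6 arrays. Vitellogenins lay at 8.71 in Ponceau Red array 2, 0.03 in Ponceau Red array 3, and 7.57 and 8.25 in the tartrazine arrays.

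Of the cytosolic heat shock list, chaperone and related genes of which only some are induced by protein damage, 1 gene passed in Ponceau Red. Whether that gene responds to protein damage was not tested. The gene hsp-43 (chromosome X, 6233151 to 6235543), of the small heat shock family, rose by 1.66 ± 0.20 log2 (3.17-fold; limma adjusted p = 0.0277, or 0.111 without either tartrazine array). The stress reporter hsp-16.2 was 2.35 ± 0.43 log2 higher and did not pass (limma adjusted p = 0.0775), but passed with the labelled trial as a block. Of 15 cytosolic heat shock genes 1 rose, or 3 adjusted over the list alone, 0 without either tartrazine array, 4 without Ponceau Red array 2 and 3 without array 3, when 1 also fell. Their median was 0.62 log2 (camera adjusted p = 0.00112, adjusted p = 0.994 with an estimated correlation, and camera adjusted p = 0.0694 without Ponceau Red array 3). Among the genes named by the rule that passed, the largest rise was that of ifas-1 (chromosome II, 3687791 to 3688719), by 4.11 ± 0.23 log2 (17.3-fold; limma adjusted p = 0.00519). The zinc transporter gene zipt-7.1 rose by 2.80 ± 0.26 log2 and the ceramidase gene asah-2 by 2.59 ± 0.20, calls that ended without either tartrazine array (limma adjusted p = 0.0856 and 0.0593). The gene F36H12.5 (chromosome IV, 5266774 to 5267605) fell by 5.98 ± 0.44 log2 (limma adjusted p = 0.00818, or 0.0556 without either tartrazine array). It read 2.47 and 1.48 in Ponceau Red, near or below the array medians, so the size of its fall is a lower bound. The lysozyme gene lys-7 rose by 1.61 ± 0.21 log2 (limma adjusted p = 0.106 without either tartrazine array). All these calls for single genes ended without either water array, and that of hsp-43 with the labelled trial as a block.

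Of the enzymes that act on foreign compounds, 3 lists did not pass in Ponceau Red over 6 arrays. Camera gave adjusted p = 0.28 for the cytochrome P450 genes (median -0.04 log2, or 0.18 with each array centred on its median), 0.263 for the UDP-glucuronosyltransferases (-0.08, or 0.14 so centred) and 0.247 for the glutathione S-transferases (-0.11, or 0.11 so centred). The UDP-glucuronosyltransferases passed without water array 1 (median -0.15 log2, camera adjusted p = 0.0421) and without Ponceau Red array 2 (-0.17, camera adjusted p = 0.0209, 8 falling and 1 rising). The glutathione S-transferases passed without Ponceau Red array 3 (-0.24, camera adjusted p = 0.0265, 8 falling and 0 rising). Single members fell, among them ugt-38 by 3.48 ± 0.17 log2 (limma adjusted p = 0.00515) and cyp-37A1 by 2.00 ± 0.20 (limma adjusted p = 0.0171). The call of cyp-37A1 ended without either tartrazine array. Both genes were also low in the further control implied by the authors' tables, at 1.18 for ugt-38 and 3.91 for cyp-37A1, so their falls may belong to the water arrays. The superoxide dismutase gene sod-1 fell by 1.1 ± 0.16 log2 (limma adjusted p = 0.0464, or 0.134 without either tartrazine array). The metallothionein gene mtl-1 was at -3.09 ± 0.53 log2 and did not pass (limma adjusted p = 0.0684). Ribosomal protein genes had a median of -0.25 log2, or -0.03 with each array centred on its median (camera adjusted p = 4.31e-05, and 0.0524 without water array 1 and 0.0548 without Ponceau Red array 2). Of these 78 genes 0 passed in limma, over all genes or adjusted over the list alone, while 1 fell without Ponceau Red array 2, and 3 fell and 1 rose without array 3. Histones had a median of -0.37 log2 with 0 of 49 passing, or 4 falling adjusted over the list alone, 3 falling and 1 rising without Ponceau Red array 2 and 10 falling and 7 rising without array 3 (camera adjusted p = 0.00209, and 0.0803 without water array 1 and 0.571 without Ponceau Red array 3). Muscle genes had a median of -0.40 log2 with 2 of 28 falling, or 3 falling and 2 rising adjusted over the list alone. The calls of these 2, the pharyngeal myosin genes myo-1 and myo-2, ended with each array centred on its median (limma adjusted p = 0.0662 and 0.0954) and without either tartrazine array (limma adjusted p = 0.13 and 0.143), as well as with the labelled trial as a block. Without Ponceau Red array 2, 4 muscle genes fell and 3 rose, and without array 3, 9 fell and 3 rose. For muscle, camera gave adjusted p = 0.0288, and 0.0524 without water array 1, 0.0867 without water array 2 and 0.16 without Ponceau Red array 2. All 3 lists had adjusted p = 0.994 with an estimated correlation. The other calls for single genes ended without either water array, with 0 probe sets passing in limma.

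The comparison of tartrazine with water asks the same of the second colorant. Cuticle genes were again among those that fell. The collagen genes dpy-5 (chromosome I, 5432197 to 5433051) and dpy-13 (chromosome IV, 4235617 to 4236710), both needed for normal body length, fell by 5.47 ± 0.53 and 5.36 ± 0.20 log2 (44.3-fold and 41-fold; limma adjusted p = 0.0152 and 0.00503, n = 2 arrays per group). The collagen gene col-161 fell by 5.26 ± 0.35 log2. The sperm gene nspd-10 rose by 4.76 ± 0.74 log2 (limma adjusted p = 0.0422), and T23B3.5 rose by 4.65 ± 0.33, both from readings in water below the array medians. The DNA repair gene xpa-1 rose by 2.95 ± 0.46 log2 (limma adjusted p = 0.0422). It read 3.90 and 4.20 in water and 6.98 and 7.02 in tartrazine, but also 6.69 in the further control implied by the authors' tables, described below. That implied control lay nearer to tartrazine for 1153 of the probe sets that passed and nearer to water for 55. In all, 1208 probe sets passed in limma, 143 up and 1065 down. The count was 0 without either water array, with 3425 and 3967 probe sets at an unadjusted p under 0.05, and 0 without either tartrazine array, with 4001 and 4586. It was 9690 without either Ponceau Red array, the same as over the 4 water and tartrazine arrays alone, where all 1208 passed. Of those 9690, 4448 were up and 5242 down, so the excess of falls was much smaller than over 6 arrays. With the labelled trial as a block 423 passed (25 up, 398 down), and the calls of dpy-5, nspd-10 and xpa-1 ended. From the second deposited table came a count of 2801, though its tartrazine columns are offset from its water columns.

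Of 173 cuticle collagens, 51 fell and 0 rose in tartrazine, or 103 and 3 adjusted over the list alone, with a median of -1.93 log2 (camera adjusted p = 1.45e-15, fry adjusted p = 0.0099). Of 98 moulting and hedgehog-related genes, 19 fell and 0 rose, or 52 and 1 adjusted over the list alone, with a median of -1.68 log2 (camera adjusted p = 3.78e-14). The hedgehog-related gene grl-17 fell by 5.79 ± 0.97 log2 (limma adjusted p = 0.0493, or 0.0582 with each array centred on its median). Of 88 sperm genes 6 rose and 0 fell, or 7 and 0 adjusted over the list alone, with a median of 0.55 log2 (camera adjusted p = 4.62e-07). Without either Ponceau Red array, 110 collagens fell and 18 rose, 67 moulting genes fell and 2 rose, and 37 sperm genes rose and 1 fell. Each of these lists had adjusted p = 0.739 with an estimated correlation, as had every list that passed for tartrazine. For single genes, 0 probe sets passed in limma without either water or either tartrazine array, and the call of grl-17 ended with the labelled trial as a block.

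The yolk, oocyte and germ line lists had far higher medians in both tartrazine arrays than in both water arrays. The vitellogenins lay at a median of 7.57 and 8.25 log2 above the water mean, oocyte and eggshell genes at 4.72 and 4.91, and germ line genes at 3.50 and 3.41. The differences were 8.76 ± 3.04 log2 for vit-6 (chromosome IV, 8261157 to 8266459), 6.23 ± 2.33 for cpg-2, a chondroitin proteoglycan of the eggshell, and 6.67 ± 2.23 for him-3, a component of meiotic chromosome axes. None of the 3 passed over 6 arrays (limma adjusted p = 0.151, 0.168 and 0.145), where the spread between the Ponceau Red arrays enters their error. Over the 4 water and tartrazine arrays their errors were 0.20, 0.26 and 0.23 log2 and all 3 passed (limma adjusted p = 3.29e-05, 4.54e-05 and 4.02e-05). Of 6 vitellogenins 0 passed over all genes and 6 rose adjusted over the list alone (median 7.83 log2, camera adjusted p = 0.00802, or 0.0619 with each array centred on its median). Of 24 oocyte and 24 germ line genes 0 passed over 6 arrays in limma, over all genes or adjusted over the list alone, and 7896 of all probe sets had an unadjusted p under 0.05. Without either Ponceau Red array 23 oocyte and 23 germ line genes rose and 0 and 1 fell, 6 vitellogenins rose, and 18 DNA damage genes rose. The oocyte and germ line medians over 6 arrays were 4.83 and 3.48 log2 (camera adjusted p = 2.67e-06 and 4.84e-06). DNA damage genes had a median of 1.83 log2 with 1 of 22 rising, and 1 adjusted over the list alone (camera adjusted p = 1.08e-05). Their medians moved with those of the germ line list, at 1.91 and -0.02 in the Ponceau Red arrays and 1.72 and 2.02 in tartrazine. A response to DNA damage therefore cannot be told apart from the difference in germ line genes. Each list had adjusted p = 0.739 with an estimated correlation.

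**Figure D3:**
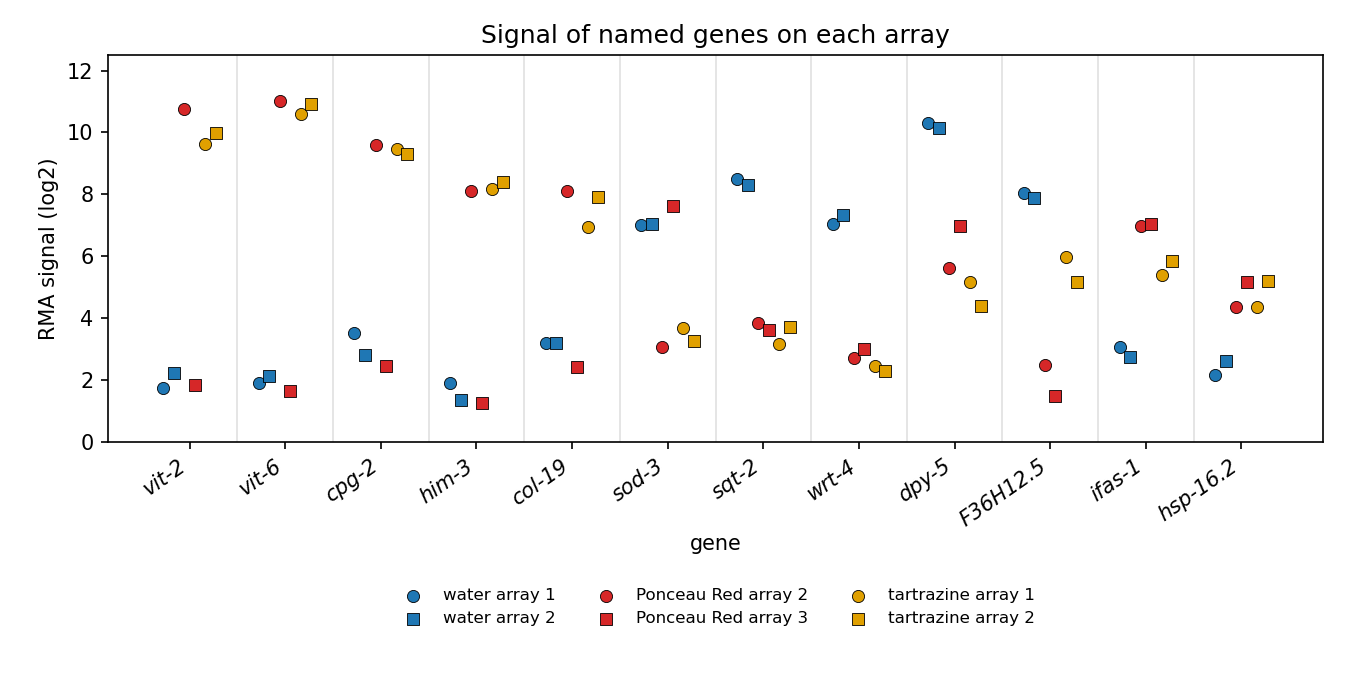
RMA signal (log2) of 12 named genes on each of the 6 arrays. The yolk gene vit-2 read 1.75 and 2.22 in water, 10.76 and 1.83 in Ponceau Red and 9.64 and 9.99 in tartrazine, while sqt-2 read 8.49 and 8.31 in water and between 3.15 and 3.84 in the 4 colorant arrays.

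Neuropeptide, muscle and mitochondrial genes were lower in tartrazine as lists, while the neurons list did not pass (median -0.26 log2, camera adjusted p = 0.0992). Of 65 neuropeptides 1 fell, or 0 adjusted over the list alone, with a median of -1.28 log2 (camera adjusted p = 3.98e-05), and nlp-11 was at -3.07 ± 1.07 log2 without passing (limma adjusted p = 0.151). Of 28 muscle genes 1 fell, or 13 adjusted over the list alone (median -0.78 log2, camera adjusted p = 0.000138). Of 40 oxidative phosphorylation genes 0 passed in limma, over all genes or adjusted over the list alone (median -0.67 log2, camera adjusted p = 0.0007). Of 78 ribosomal protein genes 1 fell, or 0 adjusted over the list alone (median -0.39 log2, camera adjusted p = 1.59e-05, or 0.389 after a further quantile normalization). Of 49 histones 3 fell, or 13 adjusted over the list alone, with a median of -0.46 log2. Camera gave the histones adjusted p = 0.00588, or 0.0715 without water array 1, 0.0652 without either Ponceau Red array and 0.0817 after the further quantile normalization. The linker histone gene hil-3 fell by 2.06 ± 0.28 log2, a call that ended with the labelled trial as a block. Few members passed over 6 arrays, where the spread between the Ponceau Red arrays enters the error. Over the 4 water and tartrazine arrays the counts falling were 45 neuropeptides, 15 muscle, 22 oxidative phosphorylation, 19 ribosomal protein and 18 histone genes, and those rising 3, 1, 6, 1 and 9. Among all 27568 probe sets 5242 fell and 4448 rose in that fit. All 5 lists had adjusted p = 0.739 with an estimated correlation. For single genes, 0 probe sets passed in limma without either water or either tartrazine array.

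Lists of the intestine and of metabolism also passed for tartrazine. Their medians were also below water in a further control implied by the authors' tables, described below. Most of the calls for these lists ended without tartrazine array 1. Of 21 intestine genes 2 fell, or 5 adjusted over the list alone (median -0.35 log2, camera adjusted p = 0.00986, or 0.0941 without that array), and the cathepsin-like protease gene cpr-5 fell by 2.47 ± 0.34 log2, a call that ended with the labelled trial as a block. Of 101 lipid genes 3 fell, or 1 adjusted over the list alone (median -0.37, camera adjusted p = 0.00986, or 0.277 without that array and 0.0505 without water array 2). Of 44 glutathione S-transferases 2 fell, also adjusted over the list alone (median -0.39, camera adjusted p = 0.014, or 0.166 without that array). Of 34 oxidative stress genes 0 passed in limma, over all genes or adjusted over the list alone (median -0.49, camera adjusted p = 0.00843, or 0.0941 without that array). The manganese superoxide dismutase gene sod-3 was at -3.57 ± 1.49 log2 and did not pass (limma adjusted p = 0.198). Of 244 C-type lectins 13 fell and 1 rose, or 20 and 1 adjusted over the list alone. Their median was -0.11 log2, which turned to 0.09 with each array centred on its median (camera adjusted p = 0.0353, or 0.058 so centred, 0.0817 after a further quantile normalization, 0.0612 without water array 1, 0.0727 without either Ponceau Red array and 0.108 without tartrazine array 2). Each of these lists had adjusted p = 0.739 with an estimated correlation. Over the 4 water and tartrazine arrays 9 intestine, 35 lipid, 15 glutathione S-transferase, 13 oxidative stress and 58 lectin genes fell, and 0, 8, 0, 1 and 24 rose. Of all 27568 probe sets 5242 fell and 4448 rose in that fit, so these counts partly reflect changes common to all genes. The cytosolic heat shock list had a median of 0.51 log2 and did not pass (camera adjusted p = 0.0945). It passed with the labelled trial as a block (camera adjusted p = 0.0498) and without tartrazine array 1 (camera adjusted p = 0.00652), while without tartrazine array 2 it lay at -0.01 log2 (camera adjusted p = 0.445). Of single genes, hsp-43 rose by 1.65 ± 0.20 log2 (limma adjusted p = 0.0245). The cytochrome P450 gene cyp-35B1 fell by 4.87 ± 0.63 log2, and its list did not pass (median -0.11, or 0.09 with each array centred on its median, camera adjusted p = 0.146, but 0.0334 without water array 1 and 0.0176 without tartrazine array 2). For single genes, 0 probe sets passed in limma without either water or either tartrazine array.

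Ponceau Red and tartrazine, given at the same dose and for the same time, were also compared directly. Between them 0 probe sets passed in limma, and 1243 had an unadjusted p under 0.05. The gene T23B3.5 was lower in Ponceau Red by -3.93 ± 0.33 log2 (95% interval -4.78 to -3.07) and F36H12.5 by -3.59 ± 0.44 (-4.75 to -2.44), while col-17 was higher by 1.63 ± 0.21 (1.09 to 2.18) and ifas-1 by 1.39 ± 0.23 (0.79 to 1.99). None of the 4 passed (limma adjusted p = 0.681), although their arrays did not overlap. For the reporter genes the difference was -0.12 ± 0.20 log2 for gst-4 (-0.65 to 0.40), -0.03 ± 0.43 for hsp-16.2 (-1.14 to 1.08) and -0.02 ± 0.63 for cyp-35A2 (-1.65 to 1.61). The interval for vit-2 ran from -11.06 to 4.02 log2. Of 27568 probe sets, 15387 had an interval within 2-fold in either direction, so for the others a difference of 2-fold is not excluded. The count was 7638 without Ponceau Red array 2, and without any other array it was 0, with between 400 and 1333 probe sets at an unadjusted p under 0.05.

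As lists, 19 of 40 passed between the colorants, 14 higher and 5 lower in Ponceau Red, with 0 members passing in limma over all genes or adjusted over the list alone, and 1243 of all probe sets at an unadjusted p under 0.05. Without Ponceau Red array 2 members did pass, among them 67 collagens, 47 neuropeptides and 45 moulting genes higher and 30 sperm, 23 oocyte and 22 germ line genes lower in Ponceau Red. Each had an adjusted p between 0.66 and 0.806 with an estimated correlation, and 0 passed with fry. Lists that passed with any array left out were sperm (median -0.40 log2, camera adjusted p = 5.05e-10), neuropeptides (1.1, camera adjusted p = 9.41e-09), collagens (0.37, camera adjusted p = 4.29e-08), moulting (0.44, camera adjusted p = 4.42e-07), oxidative phosphorylation (0.45, camera adjusted p = 9.83e-06), muscle (0.45, camera adjusted p = 0.000141) and neurons (0.40, camera adjusted p = 0.000361). Without Ponceau Red array 3 the medians of these 7 lists, in this order, were -0.28, 0.17, 0.21, 0.11, 0.18, 0.31 and 0.07 log2. Without array 2 they were -0.52, 2.31, 0.53, 0.74, 0.74, 0.55 and 0.85.

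Unlike the sperm list, the germ line, oocyte and DNA damage lists did not pass between the colorants without Ponceau Red array 3, and the vitellogenins changed direction. Germ line genes had a median of -1.88 log2 between Ponceau Red and tartrazine (camera adjusted p = 1.04e-06), or -0.03 without array 3 (camera adjusted p = 0.821). Oocyte genes were at -2.52 (camera adjusted p = 1.11e-05), or 0.17 without it (camera adjusted p = 0.0932). DNA damage genes were at -0.90 (camera adjusted p = 8.88e-05), or 0.00 without it (camera adjusted p = 0.873). Vitellogenins were at -3.57 (camera adjusted p = 0.0219), or 0.67 without it (camera adjusted p = 0.000208, so higher in Ponceau Red), and the call ended without tartrazine array 2 (camera adjusted p = 0.157). These 4 lists had adjusted p = 0.66 with an estimated correlation. The 4 medians were -3.66, -5.30, -2.03 and -8.02 log2 without Ponceau Red array 2. Chaperones of the endoplasmic reticulum unfolded protein response were at 0.64 log2 (camera adjusted p = 0.000361), or 0.18 without array 3 (camera adjusted p = 0.07), with adjusted p = 0.66 with an estimated correlation.

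Of the remaining 7 lists that passed between the colorants, all higher in Ponceau Red, every call ended with some array left out. Lipid genes were at 0.29 log2 (camera adjusted p = 0.00512, or 0.685 without tartrazine array 1), glutathione S-transferases at 0.21 (0.00776, or 0.392 without tartrazine array 1 and 0.0723 without Ponceau Red array 3) and dehydrogenases at 0.34 (0.00847, or 0.538 and 0.0869 without the same arrays). Intestine genes were at 0.19 (0.00847, or 0.176 without tartrazine array 1, 0.476 without Ponceau Red array 2 and 0.0525 after a further quantile normalization). Nuclear hormone receptors were at 0.10 (0.0167, or 0.685 without tartrazine array 1 and 0.369 without Ponceau Red array 3). Ribosomal proteins were at 0.17 (0.0153, or 0.821 without Ponceau Red array 3), and at -0.01 after a further quantile normalization (camera adjusted p = 0.528). Proteasome genes were at 0.13 (0.0188, or 0.476 without Ponceau Red array 2, 0.0529 without tartrazine array 1 and 0.725 after a further quantile normalization). With the labelled trial as a block camera gave an adjusted p of 0.0664 for the ribosomal and 0.0664 for the proteasome genes. Their adjusted p lay between 0.66 and 0.806 with an estimated correlation.

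The responses to the colorants were correlated across probe sets (Pearson r = 0.86, Spearman rho = 0.78, covariance 0.93). Unchanged groups that share the same water arrays gave on average 0.17, 0.26 and 0.03 in 100 simulations. Probe sets that rose against water with both colorants numbered 30, where 0.20 would be expected of independent lists, and 729 fell with both, where 29.28 would be expected. Among the named genes K02E11.10 fell with both, by 5.22 ± 0.29 log2 in Ponceau Red and 5.82 ± 0.29 in tartrazine, and F08F1.4 rose with both, by 3.58 ± 0.37 (limma adjusted p = 0.068 without either tartrazine array) and 3.92 ± 0.37, calls that ended with the labelled trial as a block. These expected values leave out the shared water arrays. In 20 simulated sets of unchanged groups with shared water arrays, as many probe sets with the smallest p as were called had on average 145 higher in both and 142 lower in both, and at most 321 in the same direction. The water arrays are shared, so that whatever sets them apart enters both responses. The correlation was 0.33 without Ponceau Red array 2. A test of any difference among the 3 groups passed for 695 probe sets in limma, for 0 without any single water or tartrazine array, for 10440 without Ponceau Red array 2, for 8515 without Ponceau Red array 3 and for 173 with the labelled trial as a block.

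In the authors' deposited table for Ponceau Red, 501 probe sets had an unadjusted p under 0.05, 323 of them higher and 178 lower than control, and 0 passed a Benjamini-Hochberg adjustment of these p-values. The sums of squares of these tables fit groups of 3 and 2 arrays and do not by themselves show which group has 3. The sets of arrays compared are therefore unlike those used here. If the further array was a control, as values given below favour, the control groups are unlike. Of the 796 probe sets that passed in limma over the 6 arrays, 56 were among the authors' 501 in the same direction. Of the 1208 that passed for tartrazine, 118 were among the 1746 of the authors' tartrazine table in the same direction. The authors' tables give wrt-4 as a log2 ratio of -3.80 in Ponceau Red and -4.20 in tartrazine, and hsp-16.2 as 2.19 and 2.05. They give vit-2 as 2.07 in Ponceau Red, with an unadjusted p of 0.687 by the authors.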

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

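All tests in this part were chosen after the result was seen.

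The sums of squares in the authors' deposited tables point to a further array beside the 4 water and Ponceau Red arrays, and its values as a control follow from their ratios. These values, which entered no fit over the 6 arrays, lay far above the water arrays for genes of reproduction. The implied control exceeded the water mean by a median of 7.70 log2 over the vitellogenins, 5.35 over the oocyte and eggshell genes and 4.09 over the germ line genes. The signal of vit-2 implied for it was 8.70, against 1.75 and 2.22 in the water arrays. The values rest on the arithmetic of the tables, and no label names such an array.

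For most probe sets that passed against water, the colorant arrays and this implied control lay on one side and the water arrays on the other. That this array was a further Ponceau Red array is argued against by the values it would need. Of these, 1.60% lie more than 1 log2 outside the range of the 6 arrays, against 0.0034% for a control. The authors' tartrazine table, with 1746 probe sets, also favours a control. Its ratios differed by a median of 0.10 from those computed with the implied control included, against 0.20 with the 2 water arrays alone. The implied control correlated at 0.972 between the 2 tables. Of the 1208 probe sets that passed in tartrazine against water, the implied control lay nearer to tartrazine for 1153 and nearer to water for 55. All 17 lists that passed in tartrazine had medians on the same side of the water mean in the implied control. There the medians were -1.41 log2 for neuropeptides, -0.72 for muscle, -0.44 for oxidative phosphorylation and -0.60 for intestine genes. They were -0.50 for lipid, -0.38 for glutathione S-transferase, -0.53 for oxidative stress and 2.57 for DNA damage genes. A candidate explanation is therefore that the 2 water arrays differ from a further control of the authors, so that part of the contrast with water may belong to the water samples. Across the tested probe sets the implied control correlated at 0.753 and 0.764 with the water arrays. It correlated at 0.941 and 0.796 with Ponceau Red arrays 2 and 3, and at 0.936 and 0.940 with the tartrazine arrays. An effect of the colorants remains open, since a single implied array has no error of its own.

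The vitellogenin, oocyte and germ line lists were high in both tartrazine arrays and in Ponceau Red array 2 but near water in Ponceau Red array 3. A normalization that keeps the order of genes within an array is argued against, since the median rank of each list within the array was higher than in water by at least 33.4% of the tested probe sets in the 3 arrays, against at most 7.5% between the water arrays. A wrong label of 1 Ponceau Red array cannot be told apart from a real difference: Ponceau Red array 2 and tartrazine array 2 had 192 probe sets over 2-fold apart, fewer than the 451 of the water arrays, but no further Ponceau Red array shows which of the pair is typical. Single genes, chosen after their values were seen, set both Ponceau Red arrays apart from both tartrazine arrays, as T23B3.5 at 2.46 and 1.92 against 6.48 and 5.75, or array 3 apart from water, as sqt-2 at 3.62 against 8.49 and 8.31, which leaves open a sample from outside the series. A difference in developmental stage between the animals, whether or not due to a colorant, stays open: the moulting genes lay at -1.47 log2 in Ponceau Red array 2, -1.78 and -1.59 in tartrazine and -0.35 in Ponceau Red array 3, and the bounds that all 4 colorant arrays met were set after these medians were seen.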

How the results depend on the processing

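The replicate block by column number, the series over 4 arrays for lists and the further quantile normalization for lists were added after seeing the data, as were the fits that combine a block with fewer arrays or with the second deposited table. Counts for Ponceau Red, tartrazine and any difference stayed within 1.5 times when arrays were centred on their medians (583, 973 and 528), under a further quantile normalization, both filters on low signal, both priors and 1 probe set per gene. The count between the colorants stayed at 0 in limma under these, against 1243 at an unadjusted p under 0.05. The planned replicate block by labelled trial gave 312, 423 and 173, and 0 between the colorants, with 1632 at an unadjusted p under 0.05; it leaves changes as they are and takes 1 degree of freedom. Under a replicate block by the first number in the column names, which leaves Ponceau Red array 3 alone in its number and so without weight, the counts were 7105 (3421 up, 3684 down), 10484 (4767 up, 5717 down) and 8939. Over the 4 arrays of each comparison they were 127 for Ponceau Red and 9690 for tartrazine, or 10484 for tartrazine with the replicate block. At an adjusted p under 0.1 they were 1348, 3115 and 1295. At an unadjusted p under 0.05 with a fold of at least 1.5 they were 3633, 7430, 5120 and, between the colorants, 1043. With the second deposited table over 6 arrays they were 684, 2801, 1053 and, between the colorants, 0 (5025 at an unadjusted p under 0.05), where its tartrazine columns are offset from the others. Over its 4 water and Ponceau Red arrays Ponceau Red gave 0, and 0 with a replicate block by labelled trial, with 3472 and 2391 at an unadjusted p under 0.05 in limma, and the cause was not tested. With 1 array left out, the counts ranged from 0 to 7205 for Ponceau Red, 0 to 9690 for tartrazine, 0 to 7638 between the colorants and 0 to 10440 for any difference. A lone array is then assumed to vary like the other groups.

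Of the lists, 10 passed for Ponceau Red, 17 for tartrazine and 19 between the colorants. With an estimated correlation 0, 0 and 0 passed, and with fry 1, 5 and 0. The replicate block by labelled trial gave 10, 18 and 17, and that by column number 16, 15 and 14. With 1 array left out they ranged from 8 to 13, 15 to 18 and 16 to 24. The correlation of the responses ranged from 0.33 to 0.97 with 1 array left out, was 0.86 with the replicate block by labelled trial, added later, 0.97 with that by column number and 0.78 and 0.84 with the water arrays split between the colorants.

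Of 257 values for named genes, 53 were past the threshold, and none of these reversed. Without either water array all 53 lost it, without either tartrazine array 43, with the replicate block by labelled trial 23 and with centring 8. Among values not past it, 2 passed with the replicate block by labelled trial, 85 with that by column number, 162 without Ponceau Red array 2 and 89 without array 3. Reversed values, none of them past the threshold before, were as follows, and the cause was not tested. With the replicate block by column number, in Ponceau Red against water, hsp-4 was at -0.09 log2, hsp-6 at -0.18 and cyp-35A2 at 0.02; between the colorants col-19 was at 0.45, cyp-35A2 at 0.01, egg-1 at 0.05, mex-5 at 0.18, mex-6 at 0.10, sod-3 at -0.31 and vit-2 at 0.73. Without Ponceau Red array 3, against water, hsp-4 was at -0.03, hsp-6 at -0.07 and cyp-35A2 at 0.53, and between the colorants col-19 at 0.70, cyp-35A2 at 0.52, sod-3 at -0.40 and vit-2 at 0.94. Without Ponceau Red array 2, against water, col-19 was at -0.80, sod-3 at 0.59 and vit-2 at -0.15, and between the colorants hsp-16.2 at 0.37. Without a water array, hsp-6 was at -0.07 and cyp-35A2 at 0.30 in Ponceau Red, and cyp-35A2 at -0.29 in tartrazine. Without tartrazine array 2, cyp-35A2 was at -0.70 in tartrazine, and between the colorants cyp-35A2 was at 0.70, gst-4 at 0.02 and hsp-16.2 at 0.38. With centring cyp-35A2 was at 0.22 in Ponceau Red. With 1 array left out, values against water in Ponceau Red ranged from -0.03 to 2.17 for hsp-4, -0.07 to 0.13 for hsp-6, -3.98 to 0.59 for sod-3, -0.54 to 0.53 for cyp-35A2, -0.15 to 8.77 for vit-2 and -0.80 to 4.92 for col-19, and in tartrazine from -0.70 to 0.73 for cyp-35A2. Between the colorants they ranged from -0.27 to 0.02 for gst-4, -0.45 to 0.38 for hsp-16.2, -0.40 to 4.17 for sod-3, -0.73 to 0.70 for cyp-35A2, -7.98 to 0.94 for vit-2 and -5.02 to 0.70 for col-19. Signals near the lower end of the range, where the array medians of 2.13 to 2.40 log2 lie, limit what can be seen of falls in weakly expressed genes.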

Other observations

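All tests in this part were chosen after the result was seen.

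Some genes read higher in Ponceau Red array 3 than in the other 5 arrays. The endoplasmic reticulum chaperone gene hsp-4, a reporter of the unfolded protein response, read 6.74 log2 there and between 4.23 and 4.61 in the other 5 arrays. The nuclear hormone receptor gene nhr-6 read 8.09 there, 4.09 and 4.10 in water and between 2.38 and 2.74 in the other 3 arrays. Neuropeptide genes had a median 0.79 log2 above the water mean in this array and -0.96, -1.29 and -1.17 in Ponceau Red array 2 and the tartrazine arrays. Other genes read in this array close to their level in water. The neuropeptide gene nlp-11 read 8.29 there, 7.66 and 7.51 in water and between 4.42 and 5.03 in the others. The superoxide dismutase gene sod-3 read 7.63 there, 7.02 and 7.05 in water and between 3.06 and 3.67 in the others. These are values of 1 array without a test.

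The camera and limma tests over 6 arrays printed in this part are exceptions. Apart from the use of no block, they were fixed before the data were examined, and only the choice to print them here came after. The adult collagen gene col-19 read 8.12 in Ponceau Red array 2, 2.40 in array 3, 6.93 and 7.91 in tartrazine and 3.19 and 3.2 in water. The list of 4 adult-stage collagens that holds it did not pass in tartrazine (median -0.18 log2, mean 0.78, camera adjusted p = 0.719), and its median and test were negative while its mean was positive. The 1301 chemoreceptors had a median of 0.01 log2 against water with either colorant, with 24 falling in each and 0 rising in limma. In Ponceau Red 1 fell without either tartrazine array, 37 fell and 21 rose without Ponceau Red array 2, and 78 fell and 6 rose without array 3. In tartrazine 115 fell and 8 rose without either Ponceau Red array. Their lists did not pass (camera adjusted p = 0.337 in Ponceau Red and 0.604 in tartrazine). The chemoreceptor gene str-7 fell by 3.90 ± 0.25 log2 in Ponceau Red (limma adjusted p = 0.00606, or 0.0521 without either tartrazine array) and by 4.18 ± 0.25 in tartrazine. In Ponceau Red against water 30 of 40 lists did not pass, with medians from -0.28 to 4.31 log2, and in 7 of them median and mean differed in sign. In tartrazine 23 did not pass, with medians from -0.62 to 0.51 and 6 such lists. Between the colorants 21 did not pass, with medians from -0.16 to 0.42 and 10 such lists. Of the 30, 23 and 21 lists that did not pass, 10, 5 and 12 passed with some array left out. In Ponceau Red against water the neuropeptides passed without Ponceau Red array 2 (median 0.79, camera adjusted p = 5.86e-08) and, in the other direction, without array 3 (-0.96, camera adjusted p = 3.53e-09). In the lists that passed over 6 arrays, median and mean had the same sign in all 3 comparisons. All calls for single genes ended without either water array, with 0 probe sets passing in limma.

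Of 759 probe sets that passed in the same direction with both colorants, the control implied by the authors' tables lay nearer to water for 21 and nearer to the colorants for 738. As a list the cuticle collagens lay -1.27 log2 from the water mean in the implied control and -1.59 in the 4 colorant arrays, and the moulting list -1.69 and -1.26, so the implied control shared most of their difference from water. The 20 coding genes among them, chosen after their values were seen, include the collagens col-73, col-146, col-154, col-159 and col-161 and the hedgehog-related gene wrt-4, all lower, and the genes asah-2, cup-16, ifas-1 and spp-6, all higher. For col-146 the implied control was 8.79 log2, the water mean 8.95 and the colorant means 6.30 and 5.85. For cup-16 it was 3.14, with a water mean of 3.00 and colorant means of 4.76 and 4.81. These are among the nearest to water. On a scale from 0 at the water mean to 1 at the mean of the colorant arrays they lay at 0.06 and 0.08, while ifas-1 lay at 0.48, col-161 at 0.47, col-73 at 0.38 and wrt-4 at 0.35. These positions rest on the ratios of the authors' Ponceau Red table alone and have no error. Genes near the middle of the scale, such as ifas-1, could therefore fall on either side.

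The cytosolic heat shock list was higher in Ponceau Red than in water, with a median of 0.62 log2 and 1 of 15 genes passing. The list call ended with an estimated correlation (camera adjusted p = 0.994). Part of this may come from water arrays that differ from a further control of the authors, since the implied control lay 0.49 log2 above the water arrays over the list. For hsp-43 the implied control was 6.58, near the colorant arrays at 6.74 to 7.10. For hsp-16.2 it was 2.88, near the water arrays at 2.17 and 2.62 and below the colorant arrays at 4.34 to 5.19, so this explanation leaves the reporter itself open. No biological explanation for it was tested.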
